A study of Mus musculus with 12 samples.

How the data were processed

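The study measured RNA in mouse oocytes of 2 genotypes at 2 stages, with 3 libraries per group and 15 oocytes per tube in lysis buffer, per the labels' protocols. The labels describe standard Illumina libraries from total RNA and name the replicates as biological. The aligner, the genome build, the annotation, the counting tool and its strand setting are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies are therefore uncertain.

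Both tables were used as deposited. The value of each gene in each library was deposited by the authors on a log10 scale, as log10(normalized count + 1). Per the file headers each table also held a mean signal (the mean normalized count over its 6 libraries), a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. The mean of 10 to the power of each value, minus 1, equalled the authors' deposited mean to a relative difference of 1.4e-14. The score equalled the log2 fold change divided by its standard error, and the authors' deposited p-value equalled the two-sided normal p of that score, to within 1.2e-13 and 2.8e-15. At MII the authors' deposited adjusted p-value equalled the Benjamini-Hochberg value over 16042 genes, and 6759 genes had none. The up and down marks of the authors matched an unadjusted p under 0.05 with over 2-fold in every gene of both tables. The MII table held 22801 genes. The GV table held 3475 genes, all of which met those 2 conditions, and its adjusted p-values imply 21462 tested genes, of which 5627 would lie under 0.05 at any fold.

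Every normalized count was a whole multiple of a unit that was constant within its library (100% of values within 0.05 of a whole number), so the whole reads and size factors were recovered. These gave the depths at MII. The values carry the authors' scaling, no added reference RNA was used here, and a shift of total RNA per oocyte between groups would not appear in them.

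Because the deposited unit was log10 of normalized counts, the tests planned for raw counts were replaced by the tests planned for normalized values. A test on the recovered reads was also possible and was run only as an alternative, with limma-voom. At MII, limma 3.58.1 in R 4.3.3 with a mean-variance trend was fitted to log2(normalized count + 1) of the 6 libraries with genotype as the term, after leaving out genes with a mean normalized count under 1, and p-values were adjusted by the Benjamini-Hochberg method over 20388 genes. Fold changes are on that log2 scale. They can understate the change of low genes, and can overstate it where some libraries lie at or near 0. For Kdr at MII, limma gave -5.09 and the authors' deposited table -2.67. In data simulated for the MII comparison (20388 genes, 200 changed, 3 runs), this procedure recovered 68.3% of genes changed 4-fold and 99.3% of genes changed 8-fold, with 3.2% false calls. The simulation used a common dispersion of 0.15 for all genes, changed only genes with higher counts and had no library that stood apart. These rates may therefore not hold for the real MII comparison. At GV no test across genes was fitted, since the table held selected genes, and fold changes and adjusted p-values are those of the authors' deposited table.

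The genes named were Lsm14b, then for each stage the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, no overlap between the genotypes' libraries and a mean level of at least 10 CPM, leaving out predicted and RIKEN gene models, identifiers in place of symbols and pseudogenes, and then up to 4 members of each list with the smallest p. At GV the depth is unknown and a mean of at least 500 normalized counts was used for the level, a value set after the data were seen. The gene lists and cell type markers were fixed before the data were examined. They were ribonucleoprotein partners and processing body, deadenylation and mRNA decay, dormant maternal mRNAs, CDK1 and APC/C control, spindle and kinetochore, cohesin and separase, subcortical maternal complex and maternal effect, zona pellucida and oocyte growth, egg activation and calcium, two-cell embryo genes, p53 targets and apoptosis, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, proteasome, nuclear oxidative phosphorylation and histones. The histone list was taken by symbol pattern, which also caught H13, a signal peptide peptidase gene. Lists with at least 5 measured members were tested at MII with camera (correlation 0.01, and an estimated correlation as an alternative) and with fry, adjusted over the lists. The CCT chaperonin and mitochondrial ribosomal protein lists were added after the data were seen and adjusted together with these 18, which were adjusted among themselves.

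The alternatives at MII were a pseudocount of 0.1, no filter on low values, library size alone, a 2-fold minimum, a replicate block and leaving out each library. Alternatives added after the data were seen were a mean normalized count of at least 10, upper quartile scaling, library size without the 2 genes with the most reads, limma-voom on the recovered reads, array weights, reads thinned at random to equal size factors (totals then differed) or to equal totals, and the authors' deposited adjusted p-values. Transcript lengths, base composition and 3' UTR sequences came from the GENCODE annotation of GRCm38, matched by symbol and used for gene properties only; 97.3% of the symbols at MII matched. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.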

Results

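RNA was sequenced from pools of 15 mouse oocytes taken from the ovaries of 35-day-old C57BL/6 females. Lsm14b encodes an RNA-binding protein of the LSM14 family that is found in cytoplasmic ribonucleoprotein granules. Control oocytes (WT) carried 2 floxed Lsm14b alleles without Cre. Conditional knockout oocytes (CKO) carried the same alleles with Gdf9-Cre, a recombinase expressed in oocytes from early follicle stages. Each genotype was sampled at the germinal vesicle stage (GV, arrested before maturation) and at metaphase II (MII, the mature egg), with 3 biological replicates in each of the 4 groups, 12 libraries in all. The design asks how transcript levels in oocytes lacking Lsm14b differ from controls before and after meiotic maturation. The MII values covered 22801 genes. The reads behind them came to 93117615, 88494525 and 124872889 in WT replicates 1, 2 and 3 and to 40530314, 23077585 and 38874759 in CKO replicates 2, 3 and 4, so every WT library at MII was deeper than every CKO library. The GV values covered 3475 genes that already met an unadjusted p-value under 0.05 and a difference of over 2-fold. The 6850576 to 11606262 reads in these genes are not the depth of the GV libraries.

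Lsm14b was far lower in every CKO library than in every WT library at both stages. At GV its normalized read count was 22931 ± 6257 (SD, n = 3) in WT and 1436 ± 164 (SD, n = 3) in CKO, which left 6.26% of the WT mean. At MII the corresponding values were 11051 ± 524 and 908 ± 80.9 (SD, n = 3 each), which left 8.22%. The limma log2 difference at MII was -3.61 (SE 0.27, adjusted p = 0.00265). At GV the authors' deposited table gave an adjusted p of 4.6e-79 for Lsm14b. The individual CKO libraries held between 388 and 668 Lsm14b reads at MII and between 1334 and 2067 at GV, so the remaining signal was well above a count of 0 in each of them.

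**Figure D1:**
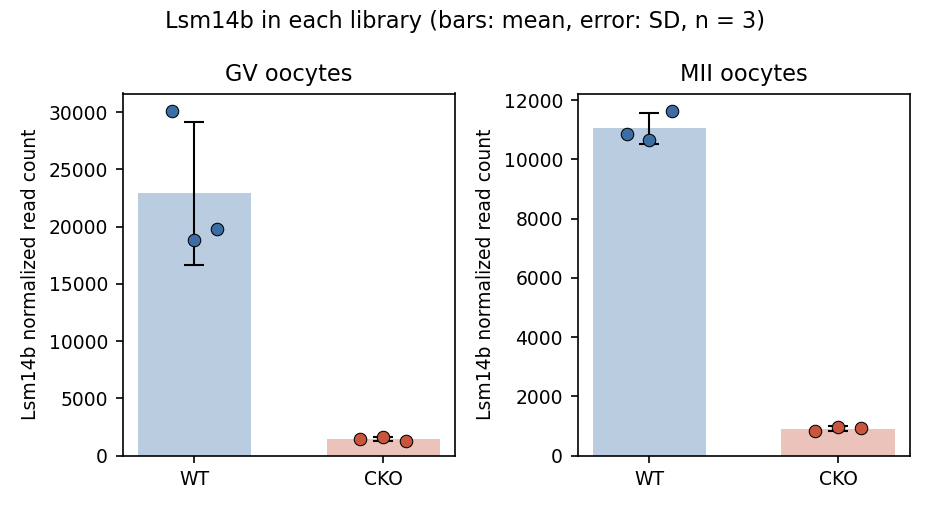
Lsm14b normalized read count in each library at GV (left) and MII (right), with points for libraries, bars for group means and error bars for the SD (n = 3). The CKO means of 1436 at GV and 908 at MII lie at 6.26% and 8.22% of the WT means.

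Against controls, GV oocytes lacking Lsm14b had more genes lower than higher. The authors' deposited table held 1064 genes higher and 1694 genes lower in CKO at an adjusted p under 0.05 and over 2-fold. Among genes with a mean of at least 500 normalized counts, the largest rises included Chrdl1, which encodes a secreted antagonist of bone morphogenetic proteins, Sycp3, a component of the synaptonemal complex of early meiosis, and Krt79, a keratin. Chrdl1 went from 1115 ± 1100 normalized counts in WT to 14025 ± 1817 in CKO (SD, n = 3 each). Sycp3 went from 283 ± 139 to 2810 ± 806 and Krt79 from 136 ± 33.3 to 2172 ± 563 (SD, n = 3 each). Mfhas1 rose from 683 ± 234 to 6395 ± 414, and Pdha2, the testis-type subunit of pyruvate dehydrogenase, from 184 ± 86.6 to 1637 ± 573 (SD, n = 3 each). Hdx, Tceal8 and Stambpl1 were under 50 normalized counts on average in WT and at 1635 ± 449, 1304 ± 569 and 1489 ± 304 in CKO (SD, n = 3 each). Among the largest falls at that level, Ece1, the endothelin-converting enzyme, went from 7518 ± 489 to 343 ± 25.2 normalized counts, the cell polarity gene Pard6g from 3882 ± 38.4 to 174 ± 49.7, and Pax5, a transcription factor of B cells, from 12770 ± 2485 to 295 ± 211 (SD, n = 3 each). The alkaline phosphatase gene Alpl fell from 1481 ± 80.2 to 23.5 ± 22.6 (SD, n = 3 each). Lower too were the VEGF receptor gene Flt1, from 1079 ± 390 to 46.9 ± 26.3, and the ephrin gene Efna4, from 1402 ± 108 to 77.0 ± 18.3 (SD, n = 3 each). Rapgef3, a guanine nucleotide exchange factor activated by cyclic AMP, fell from 2361 ± 2.54 to 130 ± 54.5, and the RNA-binding protein gene Msi2 from 1877 ± 88.0 to 62.5 ± 57.3 (SD, n = 3 each). In the authors' deposited table these 16 genes had log2 fold changes between 3.16 for Pdha2 and 5.59 for Hdx on the rising side and between -4.18 for Rapgef3 and -5.98 for Alpl on the falling side. Of the 2758 genes, 2521 (91.4%) had no overlap between the WT and the CKO libraries, where chance gives 10%. These genes had been selected for a difference. Because the table held only selected genes, no model across genes was fitted at GV, and absence from it means only that a gene did not meet the selection.

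Several groups of genes chosen in advance contained members that were called at GV. Over all genes the authors' deposited table called 2758, and its adjusted p-values imply 21462 tested genes. Some calls are therefore due in a list of any kind, and no list was tested against this share. In the list of ribonucleoprotein partners and processing body components, 3 of 28 genes were higher, 1 was lower and 24 were not called. Pabpc1, the cytoplasmic poly(A)-binding protein, went from 2539 ± 1021 to 22277 ± 2752 normalized counts (SD, n = 3 each). Patl2, an oocyte ribonucleoprotein, went from 5801 ± 714 to 23420 ± 744, and the RNA helicase gene Ddx6 from 3661 ± 878 to 9548 ± 577 (SD, n = 3 each). Dcp1a, an activator of mRNA decapping, fell by 1.29 on the log2 scale in the authors' deposited table, and it was also the 1 gene called among the 20 dormant maternal mRNAs. In the list of deadenylation and mRNA decay, 5 of 29 genes were lower and none was higher. Pabpn1l, a poly(A)-binding protein of oocytes and early embryos, went from 25480 ± 1386 to 2233 ± 585 (SD, n = 3 each). Cnot3 and Cnot6, subunits of the CCR4-NOT deadenylase, went from 63924 ± 7312 to 26807 ± 1566 and from 3577 ± 286 to 1273 ± 114 (SD, n = 3 each). Tut7, a terminal uridylyltransferase, and Exosc10, an exosome nuclease, were also lower. In the list of CDK1 and APC/C control, 2 of 42 genes were higher and 2 lower. Wee1, the kinase that inhibits CDK1, rose from 2927 ± 1164 to 9204 ± 2172 (SD, n = 3 each). Cdc25c, a phosphatase that activates CDK1, rose by a log2 fold change of 1.06 in the authors' deposited table. Gpr3, the receptor that keeps cyclic AMP high during meiotic arrest, fell from 27050 ± 9814 to 6935 ± 207, and the phosphatase gene Cdc14b from 2136 ± 656 to 821 ± 157 (SD, n = 3 each).

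Among the other lists at GV, 3 of 23 genes of the subcortical maternal complex and maternal effect list were higher and none lower. These were Nlrp14, at 246410 ± 18379 normalized counts in WT and 525230 ± 50899 in CKO, the histone demethylase gene Kdm1b, at 31948 ± 4199 and 67682 ± 7830, and Trim28, at 7737 ± 224 and 18950 ± 1081 (SD, n = 3 each). The oocyte transcription factor gene Nobox rose from 78179 ± 1379 to 233860 ± 34434 and Sohlh2 fell from 684 ± 178 to 305 ± 145 (SD, n = 3 each). The other 22 of 24 genes of the zona pellucida and oocyte growth list were not called. The spindle list had 1 call in 36 genes, the centromeric histone gene Cenpa, and the cohesin list had 2 in 15, with Smc1a higher and Pds5a lower. The calcium channel genes Orai1 and Trpv3 were lower and the calcineurin gene Ppp3ca was higher among 21 genes of egg activation. Of 25 two-cell embryo genes, 3 were higher. These were Sp110, Zscan4d and Usp17lb, the last listed at 0 in every WT library, and both Zscan4d and Usp17lb have near-identical copies, so their reads are uncertain. Of 27 p53 and apoptosis genes, 2 were higher and 6 lower; Trp53 rose by a log2 fold change of 1.33 and its relative Trp73 fell by 2.27 in the authors' deposited table. The authors' deposited table also called 1 of 13 mitochondrially encoded mRNAs (mt-Co1, log2 1.18), and 5 higher and 3 lower of 89 cytosolic ribosomal protein genes. It further called 1 higher (Psmd14) and 1 lower (Psmg3) of 45 proteasome genes, 3 higher and 1 lower of 72 nuclear genes of oxidative phosphorylation, and 1 higher and 5 lower of 62 histone genes. Rpl6 and Rpl6l, both among the ribosomal calls, are near copies of each other, and their values are uncertain.

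Among markers of other cells at GV, calls fell in the theca, stroma and endothelium list and the blood and immune list. None of 25 cumulus and granulosa markers and none of 7 sperm and early embryo markers was called. Of 13 theca, stroma and endothelium markers, 4 were lower in CKO. The angiopoietin-family receptor gene Tie1 went from 1290 ± 508 to 264 ± 125 normalized counts, the VEGF receptor gene Kdr from 213 ± 78.5 to 0 in every CKO library, Pdgfra from 76.2 ± 85.2 to 1.14 ± 1.97, and Col1a2 from 15.9 ± 7.89 to 0 in every CKO library (SD, n = 3 each). Of 12 blood and immune markers, C1qb was lower, at 1869 ± 174 in WT and 807 ± 68.2 in CKO, and Cd68 was higher, at 94.7 ± 13.3 and 270 ± 84.1 (SD, n = 3 each).

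At MII, 1 of the 6 libraries stood apart from the others. WT replicate 3 had Spearman correlations across genes of 0.834 to 0.885 with the other 5 libraries, which correlated with each other at 0.907 to 0.965. The gene model CT010467.1 took 24.3% of its reads, against 6.56% to 11.8% in the other 5, and Gm42418 took 5.21%, against 0.482% to 1.25%. The first principal component (38.9% of variance over 15336 genes) separated this library from the rest. The second (26%) separated WT replicates 1 and 2 (-127.3 and -120.4) from the CKO libraries (45.25 to 73.73). On the second component WT replicate 3 lay at 80.59, on the side of the CKO libraries. The Lsm14b value of WT replicate 3, 11641 normalized counts, was that of a WT library.

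**Figure D2:**
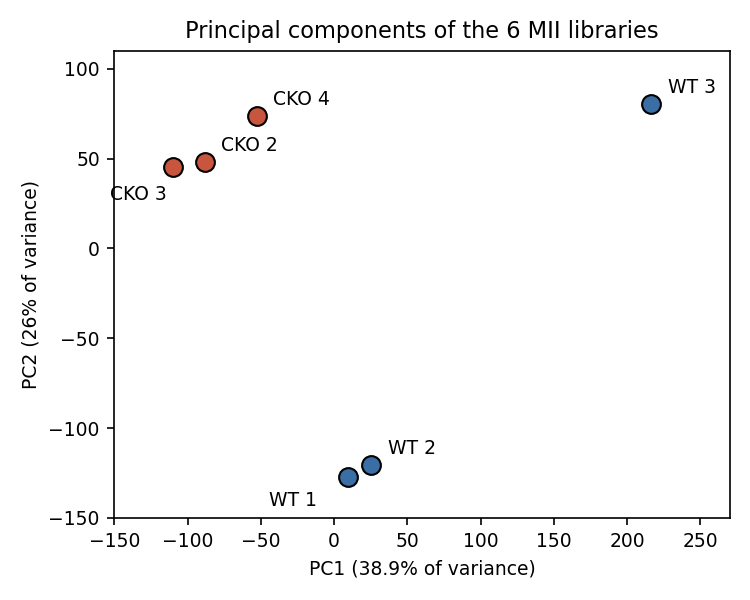
First and second principal components of the 6 MII libraries, from log2(normalized count + 1) of 15336 genes, with 1 point per library and axes in component units. WT replicate 3 lies at 216.3 on the first component, where the other libraries lie between -110.1 and 25.46. On the second component it lies at 80.59, on the side of the CKO libraries (45.25 to 73.73).

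Mature eggs lacking Lsm14b also differed from controls, and 106 genes were higher and 202 lower in CKO by limma at an adjusted p under 0.05, of 20388 tested. Among genes of at least 10 CPM, the largest rises included Cd9, the tetraspanin needed for gamete fusion, which went from 186 ± 147 normalized counts in WT to 2831 ± 466 in CKO (SD, n = 3 each; log2 difference 4.19, SE 0.55, adjusted p = 0.0121). Pabpc1 rose from 414 ± 192 to 5794 ± 1447 (SD, n = 3 each; log2 difference 3.91, SE 0.45, adjusted p = 0.00912). Mfhas1 rose from 764 ± 273 to 8804 ± 1830 (SD, n = 3 each; log2 difference 3.57, SE 0.35, adjusted p = 0.00539). Chrdl1, the mitochondrial protein gene Chchd2, Rps4l, the zinc transporter gene Slc30a2 and the cholesterol transfer gene Stard4 rose by log2 differences between 3.10 for Stard4 and 4.53 for Chrdl1. Over the fits with a library left out and the fit with array weights, the log2 difference ranged from 3.73 to 4.92 for Cd9, 3.44 to 4.53 for Pabpc1, 3.37 to 5.19 for Chrdl1, 3.75 to 5.08 for Chchd2 and 2.64 to 3.91 for Slc30a2. The largest fall at that level was that of Pard6g, from 2284 ± 1682 to 31.4 ± 21.5 (SD, n = 3 each; log2 difference -6.28, SE 0.82, adjusted p = 0.0122). The potassium channel gene Kcnh3 fell by a log2 difference of -5.25 (SE 0.43, adjusted p = 0.00265) from a WT mean of 3806 ± 1551 (SD, n = 3). Znhit2 fell from 3525 ± 468 to 209 ± 48.6 (SD, n = 3 each; log2 difference -4.09, SE 0.36, adjusted p = 0.00265). Alpl, the sulfotransferase gene Chst11, Pax5, the ephrin gene Efna1 and Tmem9 fell, with log2 differences between -4.18 for Tmem9 and -5.08 for Alpl. Over the same fits the ranges were -6.74 to -5.44 for Pard6g, -5.97 to -4.56 for Alpl, -5.45 to -3.95 for Chst11 and -5.61 to -3.68 for Pax5. All 308 called genes had no overlap between the genotypes' libraries, as did 22.4% of all tested genes, where chance gives 10%. Without WT replicate 3 the counts were 266 higher and 624 lower, with 248 of the 308 calls among them. Pard6g, Chst11 and Pax5 then had adjusted p of 0.0556, 0.0797 and 0.0941. Without any other single library limma called 0 genes, with 971 to 1278 higher and 1409 to 1729 lower at an unadjusted p under 0.05. Reads thinned to equal size factors gave 63 higher and 127 lower. Limma-voom on recovered reads gave 91 higher and 80 lower, with 148 of the 308 calls among them, so the excess of lower genes was absent from that fit. The authors' deposited table called 738 higher and 1113 lower.

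The RNA-regulating lists at MII held calls in both directions. Over all genes limma called 308 of 20388 at MII, and the counts of calls per list were not tested against this share. Of 28 measured ribonucleoprotein partners and processing body genes, limma called 2 higher (Pabpc1 and Patl2), none lower and 26 not past the threshold. Adjusted over the list alone, 3 were higher and 1 lower, and without WT replicate 3 limma called 4 higher over all genes. Patl2 was at 920 ± 317 normalized counts in WT and 3651 ± 596 in CKO (SD, n = 3 each; log2 difference 2.03, SE 0.35, adjusted p = 0.0269). Ddx6 had a log2 difference of 1.89 (SE 0.46, adjusted p = 0.0767), or 2.52 with array weights, with an adjusted p of 0.0346 without WT replicate 3, and Dazl, an RNA-binding translational regulator, had -1.63 (SE 0.39, adjusted p = 0.0737). Of 29 deadenylation and decay genes, 2 fell (Pabpn1l and Cnot6) and 27 were not past the threshold. Adjusted over the list alone, 5 were lower and none higher, and without WT replicate 3 limma called 4 lower over all genes. Pabpn1l went from 10206 ± 6379 to 555 ± 102 normalized counts (SD, n = 3 each; log2 difference -4.04, SE 0.43, adjusted p = 0.00796) and Cnot6 from 1631 ± 702 to 321 ± 53.7 (SD, n = 3 each; log2 difference -2.27, SE 0.42, adjusted p = 0.0336). The camera set test gave adjusted p = 0.158 for the first of these lists and 0.0875 for the second, and 0.618 for both with an estimated correlation. None of the 20 dormant maternal mRNAs was called over all genes and 2 were lower adjusted over the list alone, while camera placed the list lower as a whole (adjusted p = 0.00618). That call was lost with an estimated correlation (adjusted p = 0.651) and without WT replicate 3 (adjusted p = 0.186). The fry test, which sets a list against no change and not against other genes, gave adjusted p = 0.258. Fbxo43, an inhibitor of the anaphase-promoting complex, had a log2 difference of -1.73 (SE 0.44, adjusted p = 0.0883) and Btg4, an adaptor of the CCR4-NOT deadenylase, of -1.25 (SE 0.47, adjusted p = 0.226).

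Cell cycle genes changed singly at MII. Of 41 measured genes of CDK1 and APC/C control, 2 rose (Wee1 and Fbxo5), 1 fell (Ppp1cc) and 38 were not past the threshold. Adjusted over the list alone, 2 were higher and 4 lower. Wee1 was at 1373 ± 859 normalized counts in WT and 9186 ± 2652 in CKO (SD, n = 3 each; adjusted p = 0.0336), with a log2 difference of 2.28 without WT replicate 3 and 3.44 without WT replicate 1. Fbxo5, which encodes the APC/C inhibitor EMI1, was at 1709 ± 360 and 5286 ± 453 (SD, n = 3 each; log2 difference 1.65, SE 0.30, adjusted p = 0.0298). Ppp1cc, a catalytic subunit of protein phosphatase 1, went from 2463 ± 299 to 592 ± 154 (SD, n = 3 each; log2 difference -2.08, SE 0.34, adjusted p = 0.0246). Gpr3 had a log2 difference of -1.36 (SE 0.32, adjusted p = 0.0754). None of 35 spindle genes and none of 13 cohesin genes was called over all genes. Adjusted over the list alone, no spindle gene was called, and 1 cohesin gene was higher and 2 were lower. Without WT replicate 3, Smc1a was called over all genes (adjusted p = 0.0494). The microtubule depolymerase gene Kif2c had a log2 difference of 1.18 (SE 0.28, adjusted p = 0.0735), Pds5a of -1.94 (SE 0.51, adjusted p = 0.0989) and Smc1a of 1.79 (SE 0.51, adjusted p = 0.116). The 3 lists had camera adjusted p = 0.965, and the cohesin list had a median log2 difference of 0.06 while camera placed it lower.

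Kdm1b was the 1 gene of 22 measured in the subcortical maternal complex and maternal effect list that limma called, at 10595 ± 675 normalized counts in WT and 28999 ± 1745 in CKO (SD, n = 3 each; log2 difference 1.45, SE 0.25, adjusted p = 0.0277). Adjusted over the list alone, 4 genes were higher and 1 lower, without WT replicate 3 limma called 2 higher over all genes, and camera placed the list higher (adjusted p = 0.0403, and 0.618 with an estimated correlation). The fry adjusted p was 0.0284, and 0.0825 with library size alone. Nlrp14 had a log2 difference of 1.35 (SE 0.31, adjusted p = 0.0662) and Khdc3, a member of the subcortical maternal complex, of 3.46 (SE 0.77, adjusted p = 0.0612), or 4.36 without WT replicate 3 (adjusted p = 0.0346) and 2.71 without WT replicate 1. In the zona pellucida and oocyte growth list, 2 of 22 genes rose (Cd9 and Nobox) and 4 were higher and 1 lower adjusted over the list alone. The camera adjusted p of this list was 0.158, and 0.0355 without WT replicate 3 (0.663 with an estimated correlation). Nobox was at 35534 ± 14614 in WT and 135350 ± 12001 in CKO (SD, n = 3 each; log2 difference 2.02, SE 0.38, adjusted p = 0.0336), and the zona glycoprotein gene Zp3 had a log2 difference of 1.25 (SE 0.29, adjusted p = 0.0682). None of 20 egg activation, 17 two-cell embryo, 23 p53 and apoptosis or 51 histone genes was called over all genes. Adjusted over the list alone, 1 two-cell gene was higher and 2 were lower, 1 p53 and apoptosis gene was higher, and no egg activation or histone gene was called. Without WT replicate 3, limma called 1 two-cell gene higher and 2 lower, 2 p53 and apoptosis genes lower and 2 histone genes lower over all genes. The p53 and apoptosis list then had a fry adjusted p of 0.00497 (0.0990 with all libraries) and a camera adjusted p of 0.825.

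Genes of protein synthesis and energy metabolism had few single calls at MII, as did all tested genes (308 of 20388). Of 88 ribosomal protein genes, Rps4l and Rpl5 rose (3 higher adjusted over the list alone), none of 44 proteasome genes was called over all genes or over the list alone, and of 72 nuclear oxidative phosphorylation genes Atp5pb rose (1 higher adjusted over the list alone). Without WT replicate 3 limma called 3 proteasome and 2 oxidative phosphorylation genes higher over all genes. Rpl5 was at 1052 ± 175 normalized counts in WT and 4000 ± 1161 in CKO (SD, n = 3 each; log2 difference 1.89, SE 0.34, adjusted p = 0.0304, and 0.0504 without WT replicate 3). The camera adjusted p for these 3 lists was 0.186, 0.0875 and 0.158, and without WT replicate 3 it was 0.000913, 0.000335 and 0.00122, with the lists higher in CKO. With an estimated correlation those values were 0.664, 0.663 and 0.664. The 13 mitochondrially encoded mRNAs had a median log2 difference of -0.91, with no single call over all genes or over the list alone, and camera placed the list lower (adjusted p = 0.00455). That call was lost with an estimated correlation (adjusted p = 0.651) and without WT replicate 3 (adjusted p = 0.290, median -0.37). The fry test against no change gave adjusted p = 0.362. The summed normalized count over the list was 647120 in WT replicate 3, where the other 5 libraries held 132010 to 282910.

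Of the markers of other cells measured at MII, 1 was called over all genes. The 15 cumulus and granulosa markers in the data summed to 54.0 to 82.1 CPM in the 6 libraries, with no call over all genes or over the list alone, and the aromatase gene Cyp19a1 was their most abundant member in WT replicate 3 at 3071 normalized counts. Those with the smallest p were low, at a mean of at most 1.15 CPM. Ptgs2, Fshr and Inhba had log2 differences of 4.57, 4.25 and 3.57 (adjusted p = 0.170, 0.181 and 0.245) and Has2 of -3.22 (adjusted p = 0.336). The complement gene C1qb was the marker called, at 1482 ± 428 normalized counts in WT and 147 ± 42.7 in CKO (SD, n = 3 each; log2 difference -3.32, SE 0.45, adjusted p = 0.0128), and 1 of the 4 blood and immune markers tested was lower adjusted over the list alone. Of 5 theca, stroma and endothelium markers, 2 were lower adjusted over the list alone, with Tie1 at a log2 difference of -1.61 (SE 0.49, adjusted p = 0.142) and Kdr at -5.09 (SE 1.69, adjusted p = 0.174; -7.10 without CKO replicate 2 and -4.08 without CKO replicate 3). The 6 theca, stroma and endothelium markers in the data summed to 58.7 to 89.1 CPM, mostly from the adhesion gene Pecam1, at 3441 ± 610 normalized counts in WT and 3989 ± 213 in CKO (SD, n = 3 each; log2 difference 0.23, SE 0.28, adjusted p = 0.661). The 1 sperm marker measured, Odf1, was at 0 in 3 of the 6 libraries and was not called.

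**Figure D3:**
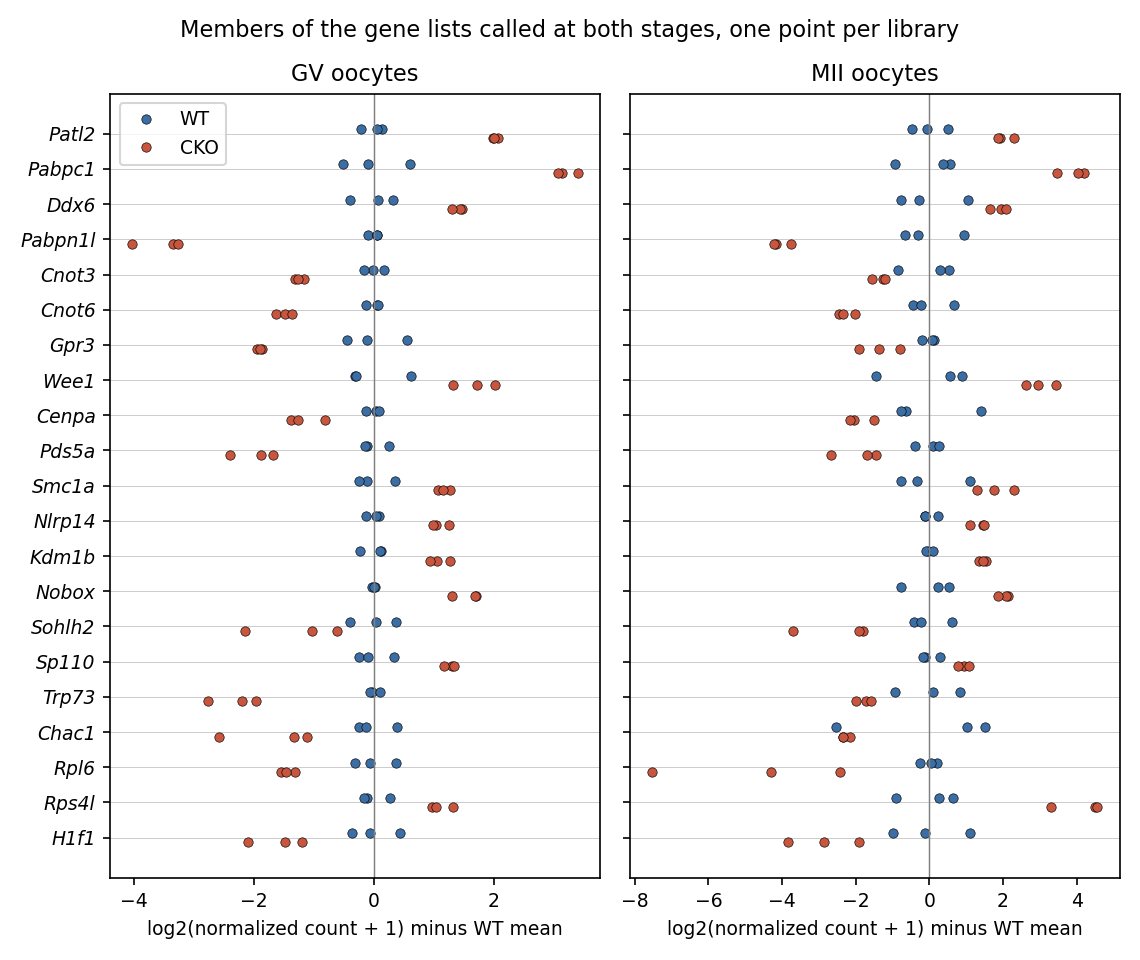
The 21 members of the fixed gene lists with an adjusted p under 0.05 at both stages in the authors' deposited table, as log2(normalized count + 1) minus the WT mean of the stage, with 1 point per library (blue WT, red CKO; the horizontal scales of the 2 panels differ). For 10 genes the CKO points lie to the right of the WT mean at both stages and for 11 to the left; for Chac1 WT replicate 3 at MII lies to the left of all 3 CKO points.

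The libraries of the 2 stages were separate, which allowed the GV calls to be followed into MII. Of the 2531 genes called at GV that were also in the MII values, 2282 (90.2%) had a log2 fold change of the same sign at MII in the authors' deposited table. The median MII log2 fold change in the authors' deposited table was 1.27 for the 966 genes higher at GV and -1.58 for the 1565 genes lower at GV, and 44.4% of all genes at MII were above 0. The authors' deposited table called 256 genes higher at both stages and 524 lower at both, where independent lists would share 40.8 and 97.8, and 5 genes lower at GV and higher at MII. Fisher's exact test of direction at GV against direction at MII over the 785 genes called at both stages gave p = 1.8e-204, across genes, which are not independent replicates. Of the 308 genes called by limma at MII, 226 were also called at GV in the authors' deposited table, all 226 in the same direction. Pabpc1, Patl2, Ddx6, Wee1, Smc1a, Nlrp14, Kdm1b, Nobox, Sp110 and Rps4l were higher at both stages, and Pabpn1l, Cnot3, Cnot6, Gpr3, Cenpa, Pds5a, Sohlh2, Trp73, Chac1, Rpl6 and H1f1 were lower at both, by the adjusted p in the authors' deposited table. The mean log2 level of the GV-higher genes minus that of the GV-lower genes was 1.52 to 1.91 in the 3 CKO libraries at MII and -1.77 to -1.28 in the 3 WT libraries (exact permutation test, two-sided p = 0.10, the smallest that 3 against 3 libraries allow). The GV and MII values had been normalized separately, so levels were compared only within a stage.

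**Figure D4:**
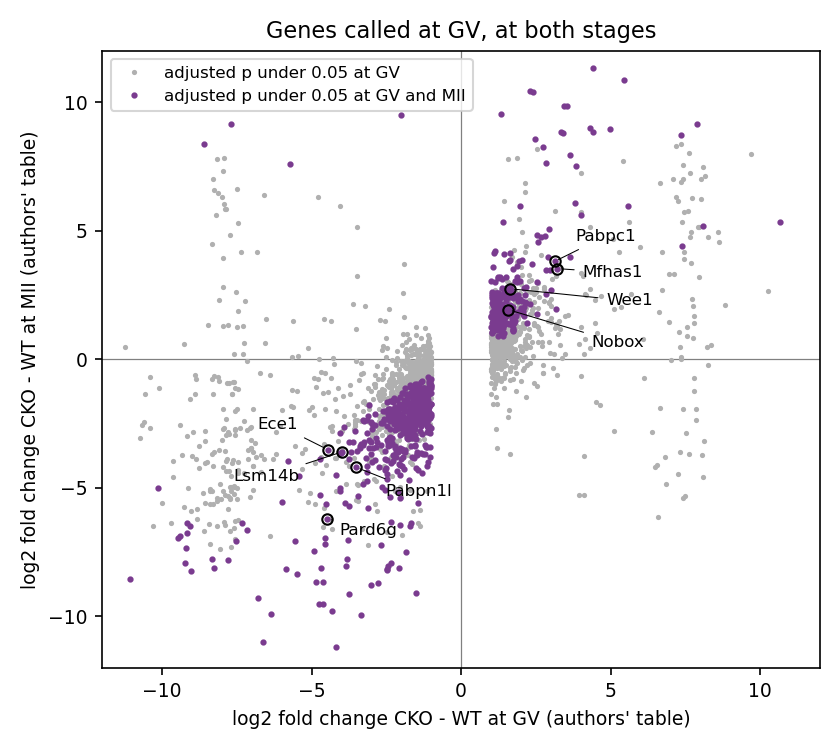
Log2 fold changes of CKO against WT in the authors' deposited table at GV (horizontal) and MII (vertical) for 2531 genes called at GV, with purple points also called at MII and 3 genes outside the plotted range of 12 on either axis. Of these genes 90.2% lie in the lower left or upper right quadrant.

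The interaction of genotype with stage, the change from GV to MII in WT oocytes and the clearance of maternal transcripts in WT were part of the design and were not fitted, because the GV values held only genes selected for a genotype difference and the stages were normalized separately.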

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

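The tests in this part were chosen after the results were seen, except the counts over splits of the libraries.

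Arhgef2, Fbxl15, Gm9939, Hrnr and Lrp3 were called lower in CKO at GV and higher in CKO at MII in the authors' deposited table. The GV minus MII difference of the authors' log2 fold changes was -11.51 for Arhgef2, -16.96 for Fbxl15, -13.33 for Gm9939, -27.13 for Hrnr and -16.82 for Lrp3. They were picked for their opposite calls, so no test of these differences is given. All 5 had 0 reads in every WT library at MII, so these fitted values are no measure of size, and Hrnr had reads in 1 CKO library at MII (58 reads). By limma their adjusted p at MII was 0.0779, 0.304, 0.200, 0.599 and 0.0922.

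Of the 10 ways to split the 6 MII libraries into 3 and 3, 1 (the real one) gave as many as the 308 limma calls, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05 the real split gave 3259 genes and the highest other 1231.

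WT replicate 3 at MII stood apart from the other 5 libraries. In it 725 of 10454 genes lay at least 8-fold below WT replicates 1 and 2 (at most 19 between that pair). The zona pellucida and oocyte growth list had a median log2 deviation of 0.68 (standard error 0.35). An even dilution by RNA of other cells lowers oocyte genes alike, so it is argued against as the only source of these falls. Whether RNA of other cells was present stays open, since scaling by size factors removes an even dilution. The cumulus and granulosa markers summed to 5214 normalized counts in WT replicate 3 and to 2964 and 2933 in WT replicates 1 and 2 (81.4, 54.0 and 55.4 CPM, with CKO replicate 4 at 82.1). A trend with transcript length and GC explained 2.94% of the variance of the deviation. A lower number of captured transcripts may contribute: with reads thinned to equal totals, 218 genes with a mean of 50 or more reads in the other WT libraries had 0 reads in it, against at most 30 in any other library (206 and 24 at equal size factors). An excess of RNA with short or no poly(A) tails stays open. The dormant mRNA list had a median deviation of 1.09, above the 0.30 that bounds the central 95% of matched lists. In contrast, 9 histone genes at a sufficient level had 1.31 (standard error 0.41), inside their bound of 1.45. The mitochondrially encoded mRNAs had a median deviation of 1.53, for which no matched range is given. CT010467.1 and Gm42418, with 24.3% and 5.21% of its reads, were not part of this test. No biological explanation was tested.

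The same genes moved at GV and MII in separate libraries. WT replicate 3 at MII is argued against as the source, since by limma 92.6% of the GV-called genes had the same sign at MII without it (88.9% with all libraries). The deeper WT libraries at MII are likewise argued against (88.8% with reads thinned to equal totals and 88.6% at equal size factors), and so is a length and GC trend, since the rank correlation of the fold changes was 0.80 before and 0.82 after both were taken out of 1865 genes. The loss of Lsm14b is a candidate explanation named by the design. Gdf9-Cre was present in the CKO and absent from the controls, so an effect of Cre itself cannot be separated from that loss here. Neither can a difference in genetic background between the Cre-positive and Cre-negative animals, or in how the genotypes were collected. None of these was tested.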

How the results depend on the processing

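At MII the counts of genes higher and lower in CKO (106 and 202) stayed within 1.5 times under a pseudocount of 0.1, no filter, a mean of at least 10, library size alone or without the 2 genes with the most reads, upper quartile scaling and a 2-fold minimum (72 to 109 higher and 150 to 218 lower). The mean of at least 10, the upper quartile, the most-read genes, voom, the weights, the thinning and the authors' values were chosen after the data were seen. Array weights gave 1297 and 1893, the authors' deposited adjusted p-values 738 and 1113, and thinning to equal size factors 63 and 127, while thinning to equal totals gave 104 and 179 and voom 80 lower; the causes were not tested. Leaving out each library in turn gave 0 to 266 higher and 0 to 624 lower. The values above 0 came without WT replicate 3 (array weight 0.198), and without each of the other 5 libraries limma called 0, with 971 to 1278 higher and 1409 to 1729 lower at an unadjusted p under 0.05. All 308 called genes kept their sign and an unadjusted p under 0.05 in each of the 6 fits with a library left out, but they had been chosen for small p in the same libraries. Fewer libraries leave less power over 20388 tests, but the fit without WT replicate 3 was as small as the others and called more genes. The number of libraries alone therefore does not account for the fits with 0 calls, and their cause was not tested. Lsm14b at MII ranged from -3.67 to -3.54 on the log2 scale with a library left out, with an adjusted p over 0.05 in all but the fit without WT replicate 3. At GV it ranged from -4.12 to -3.75 as a ratio of means. The GV counts stayed within 1.5 times at an unadjusted p under 0.05 (1378 and 2097), at an adjusted p under 0.01 (803 and 1276) and over genes still 2-fold apart with a library left out (963 to 1018 and 1578 to 1632). By limma the share of GV-called genes with the same sign at MII was 88.9% with all libraries. It ranged from 84.3% (without WT replicate 1) to 92.6% over the fits with a library left out.

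The replicate numbers were also fitted as a block at MII. Only numbers 2 and 3 occurred in both genotypes there, so WT replicate 1 and CKO replicate 4 did not inform the genotype term. Same-numbered libraries did not deviate together (correlations of 0.03 and -0.13 at MII, and -0.01, 0.02 and 0.00 at GV), so the numbers gave no pairing. With the replicate block limma called 0 higher and 0 lower (528 and 968 at an unadjusted p under 0.05, lowest adjusted p 0.587). Of the 308 called genes, 279 kept an unadjusted p under 0.05 and all kept their sign, and Lsm14b had a log2 difference of -3.63. With so few libraries behind the genotype term, the 0 calls of this fit cannot decide whether the main calls hold. A block was not fitted at GV, and tests planned for raw counts, the fit of all groups together and the clearance sets were not run.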

Other observations

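The tests in this part were chosen after the results were seen, except the length-matched test of the mitochondrial ribosomal protein genes and the test of the genes next to Lsm14b. The CCT chaperonin, the complex that folds actin and tubulin, had members higher in CKO at both stages, and the list was noticed at GV and then tested in the MII libraries. At GV the authors' deposited table called 4 of its 8 genes higher (Cct3, Cct4, Cct6a and Cct7) and none lower. At MII limma called Cct4, at 564 ± 192 normalized counts in WT and 3813 ± 774 in CKO (SD, n = 3 each; log2 difference 2.79, SE 0.37, adjusted p = 0.0124), and 5 genes were higher when adjusted over the list alone; without WT replicate 3 limma called 4 over all genes. Cct5, Cct8 and Tcp1 had log2 differences of -0.24, 0.09 and -0.07 (SE 0.29, 0.26 and 0.26). The median log2 difference was 1.17 over 7 genes with annotated length, above the central 95% of 10000 lists matched on length and level (-0.74 to 0.68). It lay above that range by less than its standard error of 0.66. A rise shared by both stages may account for it. However, the 949 genes higher at GV had a median limma log2 difference of 1.38 at MII, and the matched lists were not matched on GV calls. Neither this comparison nor the camera test therefore shows a rise particular to this list. Camera, adjusted over this list, the mitochondrial ribosomal list and the 18 tested lists together, gave adjusted p = 0.00147, a call lost with an estimated correlation (adjusted p = 0.395). Without WT replicate 3 these were 0.000676 and 0.482.

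Mitochondrial ribosomal protein genes were mostly lower where called. At GV the authors' deposited table called 14 of 78 lower and 1 higher. At MII limma called 3 of 76 lower (Mrpl2, Mrpl10 and Mrpl22) and none higher. Mrpl2 went from 12754 ± 2068 normalized counts in WT to 799 ± 350 in CKO (SD, n = 3 each; log2 difference -4.07, SE 0.35, adjusted p = 0.00265). A poorer reading of short transcripts in the CKO libraries is argued against by the length- and level-matched lists, whose median log2 difference was -0.07 (central 95% -0.44 to 0.26). The median of 73 members was -0.57, below that range by more than its standard error of 0.11. The list was added after the data were seen, so its place below the range is no independent support. Whether WT replicate 3 carries the shift of the whole list stays open, since without it the median of -0.40 (standard error 0.17) lay at the edge of the matched range (-0.38 to 0.24). The camera adjusted p, over the same 20 lists, went from 0.0126 to 0.318 without it, and it was 0.515 with an estimated correlation on all libraries.

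Cytoplasmic polyadenylation elements, 3' UTR motifs that regulate mRNA translation in oocytes, were counted in the genes called lower at MII in the authors' deposited table. The lowered transcripts may carry more of them, with a mean of 2.67 elements in 944 genes, above the central 95% of uncalled genes matched on 3' UTR length (1.99 to 2.34). Base composition as the cause is argued against, since genes matched on it too had 2.04 to 2.34. In 669 genes called higher the mean was 2.30, inside the matched range of 2.23 to 2.65. Whether WT replicate 3 is the source stays open: genes lower by limma without it had a mean of 2.43 (373 genes, matched range 1.85 to 2.25), but 2.26 (449 genes, 72.0% of the set with an annotated 3' UTR, matched range 1.80 to 2.27) with no minimum level.

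An effect of the deletion on the region around Lsm14b was tested through neighbouring genes by their order in the RefSeq annotation. Of the 20 expressed genes nearest to Lsm14b, 5 were called at GV or MII in the authors' deposited table, where 10000 random windows had a median of 4 and a 95% point of 8, which gives no sign that the region moved as a block. A passenger interval linked to the floxed alleles is outside this test, since both genotypes carry these alleles.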
